A study of Mus musculus with 110 samples.

How the data were processed

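The series holds RNA-seq of ribosome-bound RNA (IP), pulled down through an HA tag, and of the matching tissue RNA (Input), from mice under the 4 conditions and in the 4 sets named in the report. The deposited table gives read counts per gene symbol for 110 libraries. Per the submitters' processing notes, the authors aligned reads to mm10 with STAR and counted them with HTSeq. The versions, options and strand setting are not given in the sources used here, nor are the tissue, the age, and the meaning of the set names. The libraries were made with the TruSeq kit, per the labels' protocols. The labels number the replicates without stating whether each is an animal or a pool, so every p-value measures the spread between these samples.

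The table has 24060 gene rows, of which 4 with a repeated symbol were left out, and 24056 were used. Current symbols of the reference gene table cover 22600 of them, and 23923 with synonyms. No per-sample column was left unused. The table holds 0 mitochondrially encoded genes and no row for the human transgene. Each pair of libraries within a set and fraction was checked for copies, and none was found. Pairs across sets or fractions were not checked. Genes with near-identical copies (histone, ribosomal protein, Gapdh and Mzt2 genes) may gain or lose reads to their relatives, and overlapping or antisense genes to their neighbours.

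Counts were analysed with edgeR 4.0.16 in R 4.3.3. Levels of a gene are CPM after TMM scaling. Within each set and fraction, genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the 4 conditions were fitted in 1 model by edgeR's robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The contrasts were RD against ND, RZ against RD, NZ against ND and the interaction (RZ minus RD, less NZ minus ND) for each IP, and RD against ND and RZ against RD for each Input. IP was tested against Input over the 4 conditions for a change above 2-fold (log2 of 1), and members of gene lists were counted there without that minimum. A further 3 models held 2 or 4 sets and tested the difference of a contrast between the astrocyte sets, between the neuron sets and between neuron and astrocyte IPs. This makes 28 counts of genes. Standard errors come from the fold change and its test statistic.

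Of 27 gene lists fixed before the data were examined, 26 had genes in the table. They were tested with camera (limma 3.58.1, preset correlation 0.01), with camera using a correlation estimated per list, and with fry, each adjusted over the lists of a comparison. A list call is described as lost where the estimated correlation gives an adjusted p above 0.05. Members past the threshold are counted with adjustment over all genes and, where the text says so, over the list alone. In 4 signature tests the genes past the threshold between RD and ND in 1 set were given weights by direction and tested with fry for RZ against RD in the other set of the same cell type. Expected overlaps are the product of the 2 counts divided by the genes tested in both, and genes are not independent of each other.

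Genes were named by a rule fixed with the lists. For RD against ND and RZ against RD in the IPs, the 5 highest and 5 lowest genes past the threshold are named, and 3 of each for the others. A mean of at least 5 CPM over all libraries of the fit was required. For contrasts of 2 groups and for IP against Input, no overlap between the groups compared was required too. Symbols of the Gm, Rik and -ps kinds and sex-linked genes were passed over. Up to 2 genes per direction are named for each list, and Htt and Rpl22 always. A gene named in 1 comparison may be given in another. The 46 genes shared by the ZFP contrasts, the 9 of the MG IP and the low-count genes of the hSyn IP lie outside this rule and were named after their values were seen.

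In the n_ZFP_a_Rpl set and the n_ZFP_n_Rpl set, IP and Input libraries of the same condition and number deviate together from their group means, with correlations across genes of 0.4 to 0.6 over 15 pairs and 0.45 to 0.68 over 16 pairs. This pairing comes from the data, since the labels do not state it. Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors, no filter, the number as a replicate block, only the 2 groups compared, and each library left out in turn. Leaving out a group of doubted libraries was added after the data were seen. Other splits of the libraries, at most 100 per result with seed 20240501, were fitted for each count.

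The edgeR test of each comparison was run on simulated counts drawn from the real means, dispersions and library sizes. Camera, fry, the signature test and DESeq2 were simulated only for RZ against RD in the n_ZFP_n_Rpl IP. No simulation is reported for the other steps, such as the splits of the libraries. In that simulation, on 15025 genes, 0 of 100 random lists had a camera p under 0.05. Of 100 random signatures, 7 had a fry p under 0.05. Correlation between genes is not among the simulated inputs, so these rates do not measure its effect on list calls. Depth per library is given in the report, and recovery by fold size is given there beside the comparisons with few calls.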

Results

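RNA from HA-tagged ribosomes was compared between mice of the R6/2 line, a transgenic model of Huntington's disease, and NCAR mice. Each mouse group received an AAV for a zinc-finger protein (ZFP) repressor of mutant huntingtin or for Delta, the control. The 4 conditions are NCAR with Delta (ND), NCAR with ZFP (NZ), R6/2 with Delta (RD) and R6/2 with ZFP (RZ). The labels name 4 sets. In the MG set and the n_ZFP_a_Rpl set the pulled-down cell type is astrocytes, and in the hSyn set and the n_ZFP_n_Rpl set it is neurons. The pulldown is the IP and the tissue RNA is the Input, which the MG set lacks. The labels do not state which cell type carried the ZFP in each set. In all, 110 libraries were used. The MG IP has 4 libraries per condition. The hSyn set has 5 ND, 4 NZ, 3 RD and 4 RZ libraries per fraction, the n_ZFP_a_Rpl set has 4, 4, 3 and 4, and the n_ZFP_n_Rpl set has 4 of each. Assigned counts per library were 45.1 M to 72.6 M in the MG IP, 44.9 M to 57.3 M in the hSyn IP and 33 M to 44.2 M in the hSyn Input. They were 42.9 M to 50.4 M and 26.4 M to 34.2 M in the IP and Input of the n_ZFP_a_Rpl set, and 34.8 M to 46 M and 26.5 M to 35 M in those of the n_ZFP_n_Rpl set. Fold changes are log2 values with their standard error.

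The human mutant huntingtin transgene is not in the table, so the repression of the target was not measured here. Htt, the mouse huntingtin gene, was measured in every library. Its level ranged from 294 to 381 CPM in the MG IP and from 302 to 358 in the hSyn IP. It ranged from 384 to 464 in the n_ZFP_a_Rpl IP and from 392 to 482 in the n_ZFP_n_Rpl IP. Htt did not pass the threshold between RZ and RD in any IP, at 0.18 ± 0.07 in the MG set, -0.08 ± 0.05 in the hSyn set, -0.01 ± 0.04 in the n_ZFP_a_Rpl set and -0.12 ± 0.05 in the n_ZFP_n_Rpl set (adjusted p 0.206, 0.788, 0.902 and 0.0924). The labels do not state which ribosomal protein carried the HA tag. Counts of Rpl22, a ribosomal protein gene, in the Inputs ranged from 98.1 to 164 CPM in the n_ZFP_a_Rpl set. They ranged from 207 to 1030 in the n_ZFP_n_Rpl set and from 621 to 1780 in the hSyn set. Whether these reads include a tagged copy is not known, so changes of Rpl22 may be of the mouse gene or of a tag. Rpl22 fell in RD against ND in all 4 IPs. It fell by 1.29 ± 0.22 in the MG set, 1.45 ± 0.12 in the hSyn set, 0.88 ± 0.16 in the n_ZFP_a_Rpl set and 1.67 ± 0.15 in the n_ZFP_n_Rpl set. In RZ against RD, Rpl22 passed the threshold in the n_ZFP_n_Rpl IP, at 1.12 ± 0.15. It was also higher in the other IPs without passing it, at 0.42 ± 0.22 in the MG set, 0.37 ± 0.12 in the hSyn set and 0.40 ± 0.16 in the n_ZFP_a_Rpl set (adjusted p 0.33, 0.571 and 0.068). In all 3 sets with an Input, Rpl22 was higher in the IP, by 0.59 ± 0.07 in the hSyn set, 1.40 ± 0.08 in the n_ZFP_a_Rpl set and 1.48 ± 0.12 in the n_ZFP_n_Rpl set.

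Against the Input (15 IP and 15 Input libraries), the astrocyte IP of the n_ZFP_a_Rpl set was higher in all 20 astrocyte markers (median 1.83, 20 adjusted over the list alone). Cox6b2, Dcxr and Acsbg1, a fatty acyl-CoA synthetase of astrocytes, were its highest genes, at 2.24 ± 0.10, 2.18 ± 0.08 and 2.10 ± 0.04. The microglial protease Ctss and the complement gene C1qb were the lowest, at -6.95 ± 0.15 and -6.51 ± 0.12. The astrocyte call held with adjusted p = 0.000991 with an estimated correlation. So did higher transport and coupling genes (22 of 24, 0.00422), glycolysis genes (16 of 18, 0.00082) and lipid handling genes (16 of 19, 0.00599). All 21 cholesterol synthesis genes were higher (median 0.66), a call lost at adjusted p = 0.183 with an estimated correlation. Microglia markers were lower (15 of 15, median -5.89), as were endothelial and mural markers (12 of 14, median -4.23) and oligodendrocyte precursor markers (10 of 10, median -1.67). The striatal projection neuron list was split, with 11 genes higher and 15 lower of 33 (median -0.08), and 10 of 12 interneuron markers were higher (median 1.41). Pan-neuronal, cortical excitatory and oligodendrocyte markers had medians of 0.36, -0.34 and -0.90, so that general neuronal markers were not lower in this astrocyte IP. Interferon response genes were higher in 19 of 25 without a camera call. At more than 2-fold, 980 genes were higher and 2270 lower.

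In the neuron IPs, projection neuron genes were higher than in the Input for 31 of 33 genes in the hSyn set (16 and 16 libraries) and 30 of 33 in the n_ZFP_n_Rpl set (16 and 16), with medians of 0.57 and 0.77. Those calls were lost, at adjusted p = 0.229 and 0.574 with an estimated correlation. Pan-neuronal markers were higher in 15 and 16 of 16 (medians 0.60 and 0.64), calls also lost at adjusted p = 0.0746 and 0.289 with an estimated correlation. Microglia markers were lower in 15 of 15 in each set (medians -5.23 and -4.99) and oligodendrocyte markers in 14 of 14 (medians -1.68 and -1.65). Astrocyte markers were lower in 13 and 18 of 20 genes (medians -0.31 and -0.85). C1qb was at -5.93 ± 0.24 and -5.57 ± 0.13. The highest genes were histone genes such as Hist4h4, whose reads are shared with near-identical copies. Ribosomal protein genes were lower in the IP in 69, 69 and 62 of 76 genes in the hSyn, n_ZFP_a_Rpl and n_ZFP_n_Rpl sets. At more than 2-fold, 78 genes were higher and 2540 lower in the hSyn set, and 40 and 2752 in the n_ZFP_n_Rpl set.

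**Figure D1:**
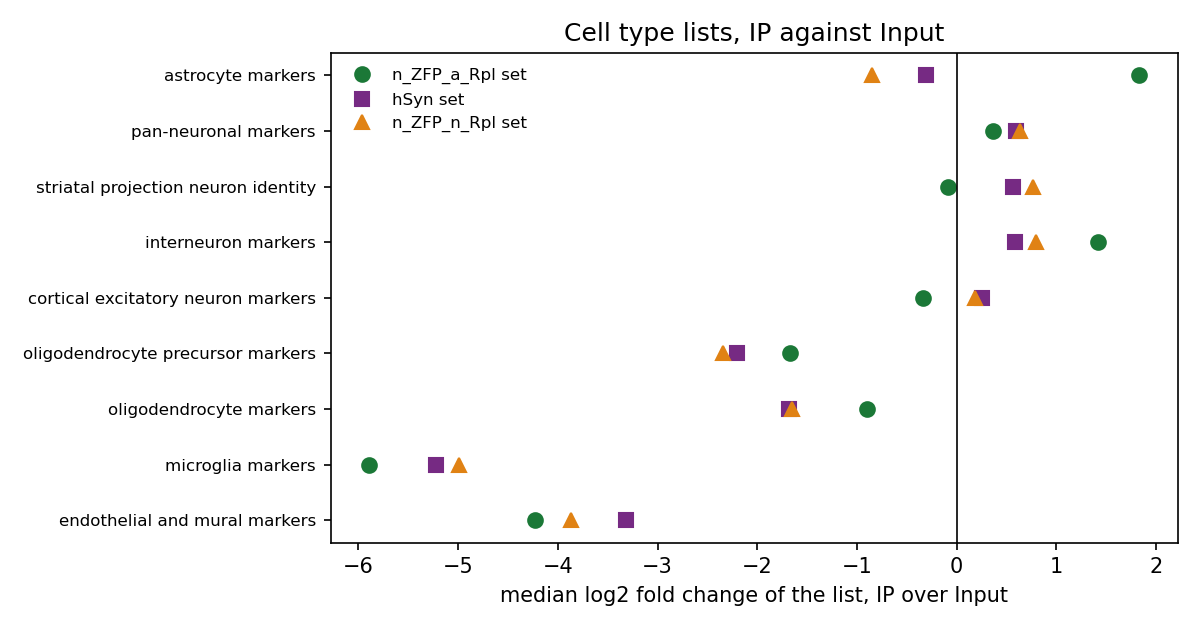
Median log2 fold change of the fixed cell type lists in the IP against the Input, for the sets with an Input.

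In the astrocyte IPs, the sodium channel subunit gene Scn4b and the calcium release channel gene Ryr1, both of striatal projection neurons, fell in RD against ND, and Tpx2, a spindle assembly factor, rose. Scn4b fell by 3.46 ± 0.22 in the MG set (4 and 4 libraries) and by 3.56 ± 0.18 in the n_ZFP_a_Rpl set (3 and 4), Ryr1 by 3.73 ± 0.15 and 3.47 ± 0.23, and Tpx2 rose by 2.50 ± 0.17 and 2.36 ± 0.11. Further highest genes were Npsr1 (4.33 ± 0.77), Emilin2 and AW551984 in the MG set and Cp (1.74 ± 0.14), Col5a2 and Chdh in the n_ZFP_a_Rpl set. Enpp6, of newly forming oligodendrocytes, rose in each (1.98 ± 0.35 and 1.86 ± 0.17). Among the lowest were Acvrl1 (-4.61 ± 0.88) and Abi3bp in the MG set and Sec14l3 (-5.05 ± 0.30), Abi3bp and Cd4 (-3.71 ± 0.20) in the n_ZFP_a_Rpl set. Projection neuron genes fell in 30 and 31 of 33 (medians -1.38 and -1.39, 30 and 31 adjusted over the list alone), with adjusted p = 0.0402 and 0.0252 with an estimated correlation. Potassium channel genes fell in 21 and 26 of 31 (23 and 26 over the list alone, estimated correlation 0.0178 and 2.58e-05), among them Kcnh4 by 2.88 ± 0.30 and 3.24 ± 0.14.

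Some genes of astrocyte function changed as well. Of 21 cholesterol synthesis genes, 15 fell in the MG set and 19 in the n_ZFP_a_Rpl set (18 and 20 adjusted over the list alone), and 0 rose. Insig1 fell by 1.19 ± 0.19 and 1.09 ± 0.13. These list calls were lost, at adjusted p = 0.233 and 0.13 with an estimated correlation. The cholesterol exporter gene Abca1 rose by 0.64 ± 0.13 and 0.90 ± 0.07 within a lipid handling list that otherwise went 3 up and 5 down in the MG set. Slc1a2, the glial glutamate transporter, fell by 0.82 ± 0.21 and 0.63 ± 0.10. Transport and coupling genes fell in 5 and 11 of 24, and astrocyte markers in 4 and 9 of 20 with 0 and 2 rising. Over all genes, 2480 of 15342 fell in the MG set and 3766 of 15246 in the n_ZFP_a_Rpl set. Reactivity genes showed no shared direction, with 2 up and 4 down of 33 in the MG set and 5 up and 7 down of 31 in the n_ZFP_a_Rpl set. Vim rose by 0.88 ± 0.28 and 1.06 ± 0.18 and Fbln5 fell by 2.14 ± 0.22 and 1.82 ± 0.16. No interferon response gene passed the threshold in either set. Among complement genes 0 and 1 fell.

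Synaptic genes fell in the same astrocyte IPs, in 10 and 15 of 20 synaptic vesicle genes and 15 and 17 of 28 glutamate and GABA receptor genes. In the n_ZFP_a_Rpl set these calls held at adjusted p = 0.00058 each with an estimated correlation. In the MG set they were lost, at 0.415 and 0.345 with an estimated correlation. Examples are Cplx2 (-1.26 ± 0.14 and -1.24 ± 0.09) and the GABA receptor subunit gene Gabrd (-1.54 ± 0.17 and -1.76 ± 0.10). Developmental transcription factor genes rose in 4 of 8 and 5 of 8, led by Wt1 (4.01 ± 0.46 and 2.58 ± 0.79) and Irx5 (2.31 ± 0.30 and 2.26 ± 0.36). Glycolysis genes fell in 4 and 9 of 18. The heat shock gene Hspa1a rose (0.74 ± 0.23 and 1.02 ± 0.21) while Trib3 fell by 2.49 ± 0.37 and 2.18 ± 0.35. Counted over all genes, 2663 rose and 2480 fell of 15342 tested in the MG set (2362 and 2632 with RLE factors, 2659 and 2859 with DESeq2), and 3141 rose and 3766 fell of 15246 in the n_ZFP_a_Rpl set. Of these, 1850 rose in each set (550 expected by chance) and 2174 fell in each (610), with 4 in opposite directions. In the MG set the share of counts from Rn45s, the ribosomal RNA precursor, also differed between ND (0.105% to 0.314%) and RD (0.0409% to 0.0661%) without overlap. In the n_ZFP_n_Rpl set it was higher in RD without overlap, at 0.00932% to 0.013% in ND and 0.0138% to 0.0179% in RD in the IP and 0.0319% to 0.0377% and 0.05% to 0.0733% in the Input.

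In the neuron IPs, RD against ND lowered activity-regulated, projection neuron and interneuron genes and raised Tpx2 again, by 2.26 ± 0.19 in the hSyn set (3 and 5 libraries) and 2.34 ± 0.15 in the n_ZFP_n_Rpl set (4 and 4). Egr2, an immediate early transcription factor gene, fell by 3.94 ± 0.64 and 5.21 ± 0.41, and Npas4 by 2.34 ± 0.42 and 2.96 ± 0.75. Activity-regulated genes fell in 16 and 17 of 17 (16 and 17 over the list alone). The call held in the n_ZFP_n_Rpl set (adjusted p = 0.0301 with an estimated correlation) and was lost in the hSyn set (0.404). Other highest genes were the efflux transporter gene Abcg2 (2.49 ± 0.15), AW551984, Pcdh20 and Sfmbt2 in the hSyn set. In the n_ZFP_n_Rpl set they were the phospholipase gene Pla2g4e (2.80 ± 0.29), Slc5a5, Sfmbt2 and AW551984. The lowest were Tgm1 (-5.77 ± 1.16), Abhd11os, Fst, Cpne9 and Prss23 in the hSyn set, and Abhd11os (-5.45 ± 0.36), Egr2, Tagln, Abi3bp and Shisa2 in the n_ZFP_n_Rpl set. Projection neuron genes fell in 31 of 33 in each set (32 over the list alone), with medians of -1.30 and -1.42 and adjusted p = 0.00539 and 0.204 with an estimated correlation, so that the second call was lost. Scn4b fell by 3.03 ± 0.12 and 3.13 ± 0.23. Interneuron markers fell in 11 and 10 of 12, with Crh down by 4.71 ± 0.56 and 3.29 ± 0.34 and Chat, of cholinergic neurons, by 2.09 ± 0.13 and 1.98 ± 0.16.

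Potassium channel genes fell in 27 and 25 of 31 in the neuron IPs (27 and 26 over the list alone, estimated correlation 0.00539 and 0.00136) and receptor genes in 15 and 18 of 28 (0.0392 and 0.0127). Syp and Stmn2 rose among pan-neuronal markers (0.70 ± 0.07 and 0.83 ± 0.10 in the hSyn set), while 9 of 16 in each set fell. Cholesterol synthesis was split, with 4 genes up and 8 down in the hSyn set and 4 up and 13 down in the n_ZFP_n_Rpl set. Tm7sf2 and Lss rose (1.23 ± 0.13 and 0.72 ± 0.10 in the hSyn set). Astrocyte markers also fell in these neuron IPs, in 18 and 14 of 20 (medians -0.89 and -0.62), with Gfap at -3.89 ± 0.58 and -1.86 ± 0.30. Astrocyte reactivity genes fell in 22 of 36 and 24 of 31, and microglia markers in 12 and 5 of 15. The camera calls for these were lost (adjusted p = 0.519 and 0.612 for astrocyte markers, 0.656 and 0.358 for reactivity genes, 0.656 for microglia in the hSyn set, with an estimated correlation). Complement and antigen presentation genes fell in 6 and 8 of 13, and interferon response genes in 0 and 10 of 25. Oligodendrocyte markers rose in 4 and 7 of 14 (Mog 0.88 ± 0.21 and 1.08 ± 0.24).

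Developmental transcription factor genes rose in 5 of 10 and 6 of 10 in the neuron IPs, among them Wt1 (3.97 ± 0.48 in the hSyn set), and 3 of 7 rose in all 4 IPs. Targets of p53 fell in 8 and 7 of 15, heat shock genes in 8 and 8 of 20 and lipid handling genes in 11 and 8 of 19. Oxidative phosphorylation genes went 8 up and 22 down of 88 in the hSyn set and 13 up and 15 down of 88 in the n_ZFP_n_Rpl set. Ribosomal protein genes rose in 13 of 76 in the hSyn set and fell in 10 of 76 in the n_ZFP_n_Rpl set. Cortical excitatory markers gave 1 up and 1 down of 10, and 0 up and 1 down. Endothelial and mural markers fell in 5 and 3 of 14, and choroid plexus and ependymal markers in 1 of 8 and 4 of 7. Oligodendrocyte precursor markers rose in 4 and 3 of 10. Over all genes, 3902 rose and 3918 fell of 15347 in the hSyn set, and 3816 rose and 3956 fell of 15126 in the n_ZFP_n_Rpl set. Across the 4 IPs, 1300 genes rose in each (37.3 expected) and 1656 fell in each (40.9), including 30 of 33 projection neuron genes, 20 of 31 potassium channel genes and 8 of 21 cholesterol synthesis genes.

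The change from ND to RD differed between neuron and astrocyte IPs for Gfap, the glial filament gene, which was lower in the neuron than in the astrocyte change (-2.79 ± 0.37), as were Abhd11os (-2.99 ± 0.25) and Shisa2 (-2.83 ± 0.25). In the astrocyte IPs Gfap did not pass the threshold (-0.12 ± 0.34 and -0.03 ± 0.17). Slc5a5 (2.00 ± 0.46), Mir6236 (1.38 ± 0.47) and the sterol reductase gene Tm7sf2 (1.35 ± 0.11) lay on the other side. Cholesterol synthesis genes were higher in the neuron than in the astrocyte change in 12 of 21 (13 over the list alone) and lower in 0, with adjusted p = 0.156 with an estimated correlation. Astrocyte reactivity genes were lower in 19 of 36, astrocyte markers in 11 of 20 and heat shock genes in 10 of 20, calls lost at adjusted p = 0.175, 0.445 and 0.156 with an estimated correlation. Projection neuron genes differed in 6 of 33, with 5 higher and 1 lower. In all, 1845 genes were higher and 1468 lower of 16038. Each cell type was pulled down in sets of its own, so a difference between cell types cannot be fully told apart from one between sets.

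**Figure D2:**
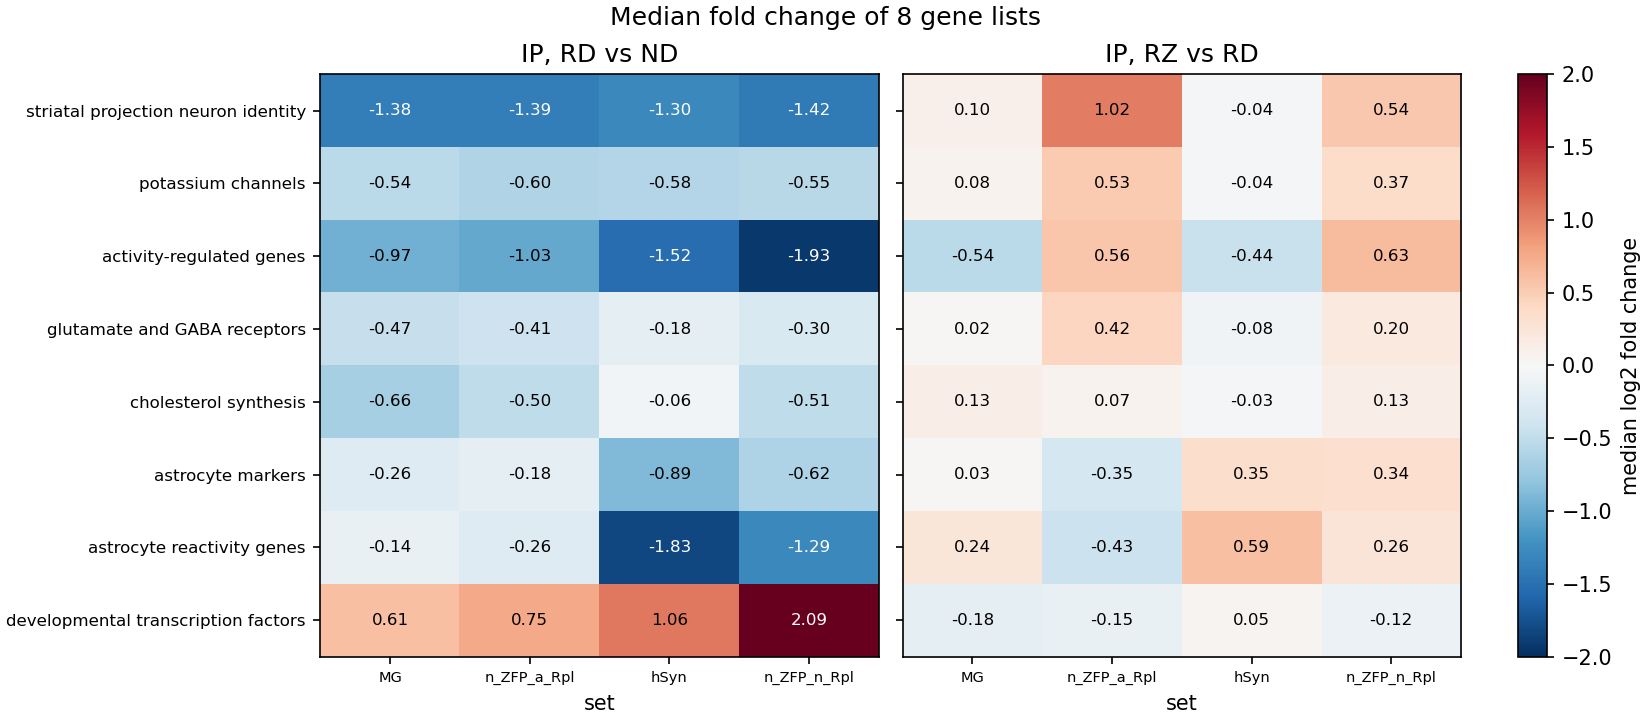
Median log2 fold change of 8 fixed gene lists in the IPs of the 4 sets, RD against ND and RZ against RD.

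In the astrocyte IP of the n_ZFP_a_Rpl set, RZ against RD (4 and 3 libraries) raised genes that had fallen in RD. Scn4b rose by 2.45 ± 0.17, Cd4 by 3.05 ± 0.20, Sec14l3 by 2.95 ± 0.32, Ptpn7 by 2.80 ± 0.21 and Pthlh by 2.36 ± 0.13. Tceal6 (-4.55 ± 0.14), Nap1l3 (-3.88 ± 0.18), the calcium pump gene Atp2b3 (-3.48 ± 0.28), the co-chaperone gene Dnajc12 (-2.56 ± 0.14) and Impdh1 (-2.41 ± 0.08) fell most. Projection neuron genes rose in 32 of 33 (median 1.02, 32 over the list alone), with adjusted p = 0.0363 with an estimated correlation. Arpp21 fell, by 0.92 ± 0.11. Potassium channel genes rose in 22 of 31 (0.000107), synaptic vesicle genes in 16 of 20 (0.000505), receptor genes in 16 of 28 (17 over the list alone, 0.000505) and pan-neuronal markers in 9 of 16 (0.0161). Kcnh4 (2.31 ± 0.14), Gabrd (1.39 ± 0.10), Cplx2 (0.96 ± 0.09) and Egr1 (2.12 ± 0.27) are examples.

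Astrocyte markers went the other way in that comparison, with 19 of 20 lower (median -0.35), a call lost at adjusted p = 0.231 with an estimated correlation. Gfap fell by 0.58 ± 0.17 and Ntsr2 by 0.61 ± 0.12. Lipid handling genes fell in 13 of 19 (Abca1 -0.61 ± 0.07) and transport and coupling genes in 15 of 24 (16 over the list alone, Kcnj10 -0.53 ± 0.15), calls lost at adjusted p = 0.231 and 0.674 with an estimated correlation. Cholesterol synthesis genes rose in 4 and fell in 2 of 21. Glycolysis genes rose in 7 and fell in 4 of 18, ribosomal protein genes rose in 18 of 76 and oxidative phosphorylation genes in 15 of 88 (9 over the list alone). In all, 2915 genes rose and 2236 fell. In the Input of the same set (4 and 3), 30 of 33 projection neuron genes rose (median 0.67, 31 over the list alone, 0.000749 with an estimated correlation), and 1 of 20 astrocyte markers rose and 2 fell. Abhd11os (3.02 ± 0.19), Sec14l3 and Fst were highest there, and Tceal6 (-1.62 ± 0.15), Nap1l3 (-1.60 ± 0.20) and Dnajc12 lowest. In the Input 1751 genes rose and 794 fell, and leaving out RD 2 gave 1677 in place of 2545.

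RZ against RD (4 and 4) changed 12 genes in the MG IP. Proteoglycan genes Prelp (-2.31 ± 0.28) and Ncan (-1.03 ± 0.12, from a mean of 525 CPM to 257) fell, as did Txlnb (-2.05 ± 0.28), Itga7 (-1.26 ± 0.22), Cyp2j6 (-1.11 ± 0.14) and the potassium channel gene Kcnn3 (-0.78 ± 0.11). Sbk1 rose, by 0.32 ± 0.05. No projection neuron gene passed the threshold, and Kcnn3 was the only gene of the 26 lists that did. Oxidative phosphorylation genes rose in 18 and fell in 6 of 89 when adjusted over the list alone, a call lost at adjusted p = 0.958 with an estimated correlation. DESeq2 called 391 genes, and 2760 had an unadjusted p below 0.05. The count moved by more than 1.5 times without RD 2 (5), RD 3 (5), RZ 1 (2043), RZ 2 (6) or RZ 4 (7). This comparison was simulated on 15234 genes, with changes planted only at a mean of at least 5 CPM and no structure among libraries. There, 76.1% of genes changed by 1.5-fold were recovered and 95.5% of those changed by 2-fold.

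Between the astrocyte IPs, the RZ against RD changes of Tceal6 (-4.02 ± 0.20), Nap1l3 (-3.69 ± 0.19) and Atp2b3 (-3.54 ± 0.27) were lower in the n_ZFP_a_Rpl set than in the MG set. Egr2 (4.28 ± 1.32), Cd4 (2.77 ± 0.37) and Ptpn7 (2.72 ± 0.33) were higher. Projection neuron genes were higher in 26 of 33 (29 over the list alone, median 1.07), a call lost at adjusted p = 0.094 with an estimated correlation. Potassium channel genes were higher in 15 of 31 (16 over the list alone, 0.00712), receptor genes in 12 of 28 and synaptic vesicle genes in 9 of 20 (0.131 each, lost). In all, 1259 genes were higher and 771 lower of 15594. The 2030 genes became 3425 without MG RZ 1 and 1272 without n_ZFP_a_Rpl RD 2.

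**Figure D3:**
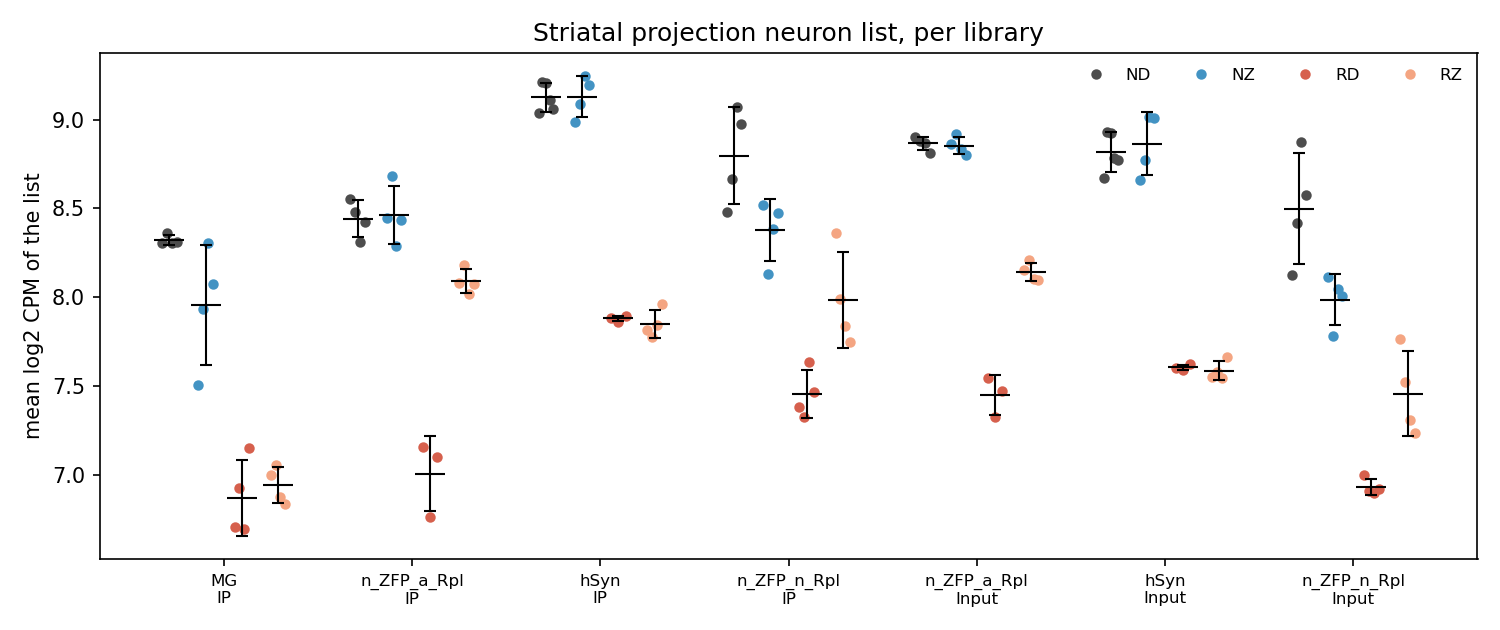
Mean log2 CPM of the striatal projection neuron list in every library, by set, fraction and condition.

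In the neuron IP of the n_ZFP_n_Rpl set, RZ against RD (4 and 4) raised interneuron, potassium channel and receptor genes and Abhd11os (4.19 ± 0.37), an antisense transcript whose counts depend on strand handling. The neuropeptide gene Cartpt (2.49 ± 0.38), Fst (2.38 ± 0.20), Ldhd (1.87 ± 0.12) and Egr2 (1.77 ± 0.41) followed. Tceal6 (-2.63 ± 0.09), Pla2g4e (-2.43 ± 0.28), Dach1 (-2.38 ± 0.19), Mzt2 (-2.36 ± 0.07) and Nap1l3 (-2.33 ± 0.09) fell most. Interneuron markers rose in 9 of 12 (median 0.83, 9 over the list alone, 0.00383 with an estimated correlation), among them Crh by 2.03 ± 0.35. Potassium channel genes rose in 16 of 31 (18 over the list alone, 0.00383) and receptor genes in 12 of 28 (15 over the list alone, 0.0057), while Kcnn3 fell by 1.54 ± 0.12. Projection neuron genes rose in 20 of 33 (median 0.54, 23 over the list alone), a call lost at adjusted p = 0.782 with an estimated correlation. RZ 1 had the highest mean of this list in RZ (8.36 log2 CPM, next 7.99) and the lowest mean of cortical excitatory markers (4.16, next 4.89), and within the groups of this IP the means of these lists ran opposite (correlation -0.86 over 16 libraries). Scn4b rose by 1.65 ± 0.22 and Ryr1 by 1.36 ± 0.23, and Arpp21 fell by 0.99 ± 0.10. Activity-regulated genes rose in 7 of 17 (9 over the list alone), a call lost at 0.305 with an estimated correlation.

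Markers of glia in that neuron IP rose in 3 of 20 astrocyte markers (Slc1a2 0.50 ± 0.14) and 7 of 24 transport and coupling genes, and 0 of 14 oligodendrocyte markers passed the threshold. Cholesterol synthesis genes rose in 6 and fell in 2 of 21. In all, 1432 genes rose and 1203 fell. In the Input (4 and 4), Ryr1 (1.59 ± 0.31), Scn4b (1.51 ± 0.20) and Ptpn7 (1.30 ± 0.33) rose most, Pla2g4e (-2.24 ± 0.26), Tceal6 (-1.12 ± 0.12) and Dach1 (-1.11 ± 0.20) fell most, and 14 of 33 projection neuron genes rose (29 over the list alone). That call was lost at adjusted p = 0.193 with an estimated correlation. The Input counts were 394 up and 131 down, and the total of 525 became 308 without RD 2, 306 without RD 3, 260 without RD 4, 336 without RZ 1 and 216 without RZ 2.

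In the hSyn IP, RZ against RD (4 and 3) changed 6 genes. Abhd11os rose by 1.26 ± 0.17, and Ncan (-0.43 ± 0.07) and Tceal6 (-0.36 ± 0.06) fell, with Itga7 and Txlnb lower at low counts. No member of any list passed the threshold. Camera called 14 lists and none held with an estimated correlation, with astrocyte markers at adjusted p = 0.218. DESeq2 called 22 genes, and 1101 had an unadjusted p below 0.05. Left out in turn, RD 1, RD 3 and RZ 2 gave 0 genes and RD 2, RZ 1 and RZ 3 gave 2, and without the doubted libraries the count was 14. In the hSyn Input (4 and 3) edgeR's quasi-likelihood test called 0 genes, 628 had an unadjusted p below 0.05 and DESeq2 called 5. Without RD 1 the count was 1. Changes were simulated among 15187 genes of the IP, planted only at a mean of at least 5 CPM. Those of 1.5-fold were recovered in 88.1% of cases and those of 2-fold in 95.5%.

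Between the neuron IPs, the RZ against RD change was higher in the n_ZFP_n_Rpl set than in the hSyn set for Abhd11os (2.93 ± 0.43), Egr2 (2.74 ± 0.78) and Cplx3 (2.56 ± 0.70). It was lower for Pla2g4e (-3.56 ± 0.96), Tceal6 (-2.26 ± 0.11) and Nap1l3 (-2.18 ± 0.11). Receptor genes were higher in 8 of 28 (15 over the list alone, 0.000187 with an estimated correlation), potassium channel genes in 10 of 31 (14 over the list alone, 0.000535) and interneuron markers in 4 of 12 (6 over the list alone, 0.0233). Projection neuron genes were higher in 10 of 33 (22 over the list alone), a call lost at adjusted p = 0.299 with an estimated correlation. Over all genes 414 were higher and 182 lower of 15660. The total of 596 became 342 without hSyn RD 1, 388 without hSyn RZ 2, 395 without hSyn RZ 3 and 369 without n_ZFP_n_Rpl RZ 2.

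The genes that changed in R6/2 in the MG set moved back with the ZFP in the n_ZFP_a_Rpl set. Of 5115 such genes, 88.2% shifted towards NCAR in RZ against RD, with a mean signed shift of -0.326 (adjusted p 6e-08 over the 4 signatures), and of the 2702 that passed the threshold 2627 moved towards NCAR and 75 away. The 7701 genes of the hSyn set shifted in the n_ZFP_n_Rpl set by -0.232 (85.9% towards NCAR, adjusted p 2.18e-07), with 2096 towards and 44 away. In the reverse direction, the n_ZFP_a_Rpl genes shifted by -0.075 in the MG set (64%, adjusted p 0.0329; the call was lost without MG RD 1, RD 3, RZ 1 or RZ 2, at -0.066, -0.062, -0.072 and -0.074), and the n_ZFP_n_Rpl genes by -0.033 in the hSyn set (53.1%, 0.41). In NCAR mice, the shifts of these 4 signatures in NZ against ND were -0.028, 0.034, 0.044 and 0.005 in the same order, with positive values in the direction of R6/2. The unadjusted fry p was 0.211, 0.0358, 0.0683 and 0.844. Of the hSyn genes in the n_ZFP_n_Rpl set, 514 passed the threshold in that direction and 200 in the other. Genes that rose with the ZFP in R6/2 in each n_ZFP set numbered 948 (277 expected by chance), and those that fell 571 (179), with 58 in opposite directions.

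In NCAR mice the ZFP changed fewer genes than in R6/2 mice in the n_ZFP sets. In the n_ZFP_a_Rpl IP (4 and 4), Tceal6 (-4.95 ± 0.14), Nap1l3 (-3.37 ± 0.17) and Atp2b3 (-3.16 ± 0.27) fell, and Egr1 (1.48 ± 0.23), Crhbp (1.33 ± 0.19) and Slitrk6 (0.86 ± 0.10) rose. Of 33 projection neuron genes 1 fell. The 183 higher and 133 lower genes, 316 in all, became 203 without ND 2, 641 without NZ 3, 151 without NZ 4, 146 in a fit of only the 2 groups and 875 with DESeq2. In the n_ZFP_n_Rpl IP (4 and 4), Dach1 (-2.43 ± 0.19), Tceal6 (-2.31 ± 0.09) and Brdt (-2.04 ± 0.10) fell and Pla2g4e (2.31 ± 0.29), Klk6 (1.56 ± 0.31) and AW551984 (1.41 ± 0.39) rose. There, 6 of 17 activity-regulated genes (12 over the list alone, median -0.78), 4 of 33 projection neuron genes (22 over the list alone) and 17 of 88 oxidative phosphorylation genes (28 over the list alone) fell, and 9 of 31 reactivity genes rose. Those calls were lost, at adjusted p = 0.347, 0.503, 0.503 and 0.503 with an estimated correlation. The mean of cortical excitatory markers, opposite to that of projection neuron genes within the groups of this IP, ranged from 3.82 to 5.55 log2 CPM in ND and from 4.98 to 5.55 in NZ. The count was 432 higher and 681 lower, with 1113 in all, 599 without ND 3, 524 without NZ 2, 638 without NZ 3 and 572 without the doubted libraries. It was 241 in a fit of only the 2 groups and 1751 with DESeq2.

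In the MG IP, NZ against ND (4 and 4) raised Npsr1 (3.87 ± 0.76), Dnah6 (1.63 ± 0.44) and Tnfaip6 (1.15 ± 0.33) and lowered Sp6 (-3.49 ± 0.67), Txlnb (-2.46 ± 0.29) and Prelp (-2.23 ± 0.28). Projection neuron genes fell in 8 of 33 (12 over the list alone), and 21 of 89 oxidative phosphorylation genes (34 over the list alone) and 19 of 76 ribosomal protein genes (29 over the list alone) rose, calls lost at adjusted p = 0.495 each with an estimated correlation. NZ 2 had the lowest mean of projection neuron genes in NZ (7.50 log2 CPM, next 7.93) and the highest of astrocyte markers (9.47, next 9.01). Rn45s took 0.105% to 0.314% of the counts in ND and 0.0306% to 0.0881% in NZ. The 565 higher and 516 lower genes, 1081 in all, became 26 without ND 1, 19 without ND 2, 127 without ND 3, 407 without ND 4, 2057 without NZ 2, 32 without NZ 3 and 50 without NZ 5. DESeq2 called 2251, and with it, with RLE factors and in a fit of only the 2 groups more genes fell than rose. In the hSyn IP (4 and 5), A2m (-5.21 ± 0.75) and Cyp2j6 (-1.34 ± 0.12) fell with 2 low-count genes, no list member passed the threshold and DESeq2 called 10.

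The effect of the ZFP differed by genotype in both n_ZFP sets. In the n_ZFP_a_Rpl IP, Cd4 (2.88 ± 0.25), Scn4b (2.44 ± 0.21) and Sec14l3 (2.43 ± 0.38) had the highest interaction and Tpx2 (-1.89 ± 0.16), Ipcef1 (-0.98 ± 0.18) and Tor3a (-0.92 ± 0.22) the lowest. Projection neuron genes were positive in 30 of 33 (32 over the list alone, 0.0209 with an estimated correlation), potassium channel genes in 18 of 31 (8.12e-05), receptor genes in 16 of 28 and synaptic vesicle genes in 12 of 20 (0.000557 each). In the n_ZFP_n_Rpl IP, Abhd11os (4.30 ± 0.45), Egr2 (3.36 ± 0.52) and Nr4a1 (2.68 ± 0.32) were highest and Pla2g4e (-4.74 ± 0.41), Klk6 (-2.02 ± 0.44) and Tpx2 (-1.49 ± 0.21) lowest. Activity-regulated genes were positive in 12 of 17 (14 over the list alone, 0.0245) and interneuron markers in 8 of 12 (0.0251). Projection neuron genes were positive in 28 of 33 (32 over the list alone), a call lost at adjusted p = 0.177 with an estimated correlation. Within the groups of this IP their mean ran opposite to that of cortical excitatory markers (correlation -0.86 over 16 libraries).

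Over all genes, 1739 were positive and 773 negative in the n_ZFP_a_Rpl set and 1281 and 708 in the n_ZFP_n_Rpl set, the latter 1989 in all against 1195 without the doubted libraries. In the MG and hSyn IPs edgeR's quasi-likelihood test called 0 genes for the interaction, with 1143 and 646 at an unadjusted p below 0.05 and 52 and 7 called by DESeq2. Without MG NZ 4, RZ 1 or RZ 4 the MG count was 1, without RD 1 it was 2 and without RD 4 it was 3, and without hSyn RZ 4 the hSyn count was 1. In the MG simulation, on 15238 genes, 41.8% of interactions of 1.5-fold and 86.6% of 2-fold were recovered, and in the hSyn simulation, on 15181, 62.7% and 85.1%. These were planted only in genes with a mean of at least 5 CPM.

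**Figure D4:**
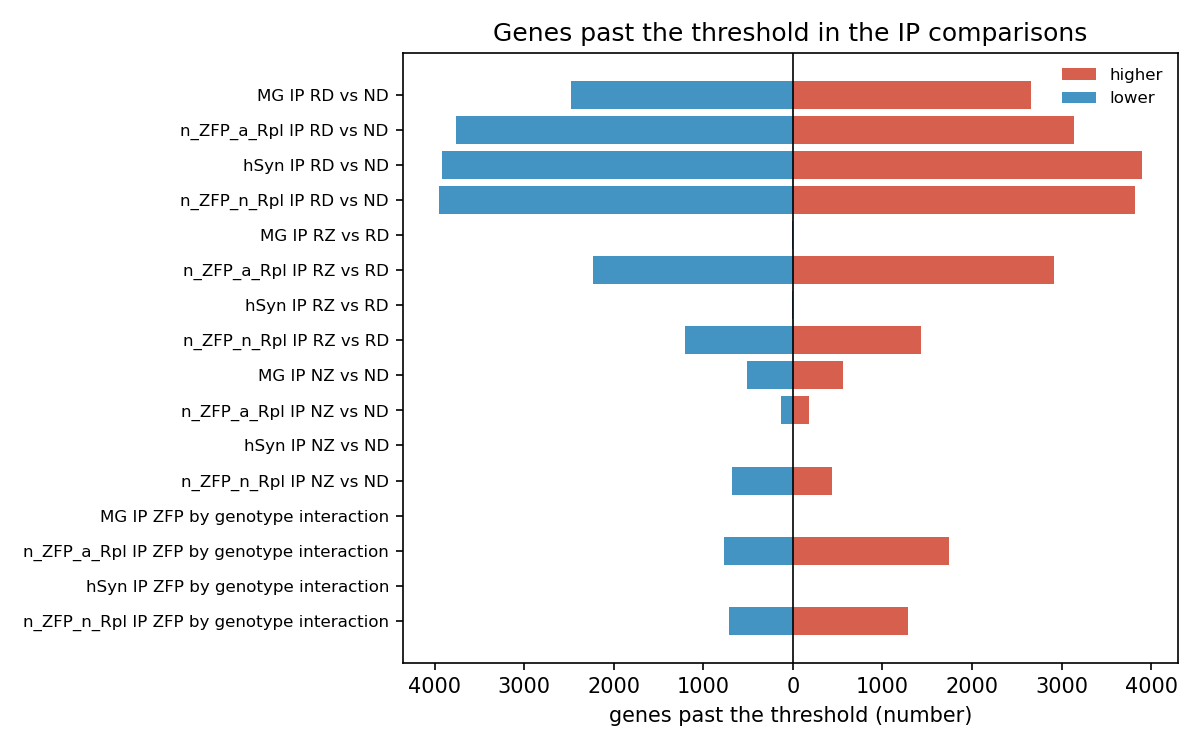
Genes past the threshold in each comparison within an IP, higher and lower.

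In the n_ZFP sets, 46 genes passed the threshold in the IPs of both genotypes and both sets with the same direction, 39 lower and 7 higher with the ZFP. This group was chosen after the values were seen. Tceal6, Nap1l3, Atp2b3, Dach1, Dnajc12, Impdh1, Mzt2 and Brdt are among the lower, and Slitrk6, Rian and Specc1 among the higher. For Tceal6 the fall in R6/2 was 4.55 ± 0.14 in the astrocyte IP and 2.63 ± 0.09 in the neuron IP, against 1.62 ± 0.15 and 1.12 ± 0.12 in the Inputs. In RZ against RD the fall was larger in the IP than in the Input for 38 of the 39 genes in the n_ZFP_a_Rpl set (medians -1.16 and -0.76) and for 39 of 39 in the n_ZFP_n_Rpl set (medians -1.03 and -0.49). The genes were picked by their fall in these IPs and not in the Inputs, which favours a larger fall in the IP. For 65 genes picked in NCAR alone, the change in the IP less that in the Input was smaller. Its medians were -0.19 and -0.31 in these sets, against -0.37 and -0.61 for the 39 genes. In the MG IP, A2m, Cyp2j6, Itga7, Kcnn3, Ncan, Olfml2a, Prelp and Txlnb were lower with the ZFP in both genotypes and Sbk1 higher, and in the hSyn IP Itga7 and Txlnb were lower in both.

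**Figure D5:**
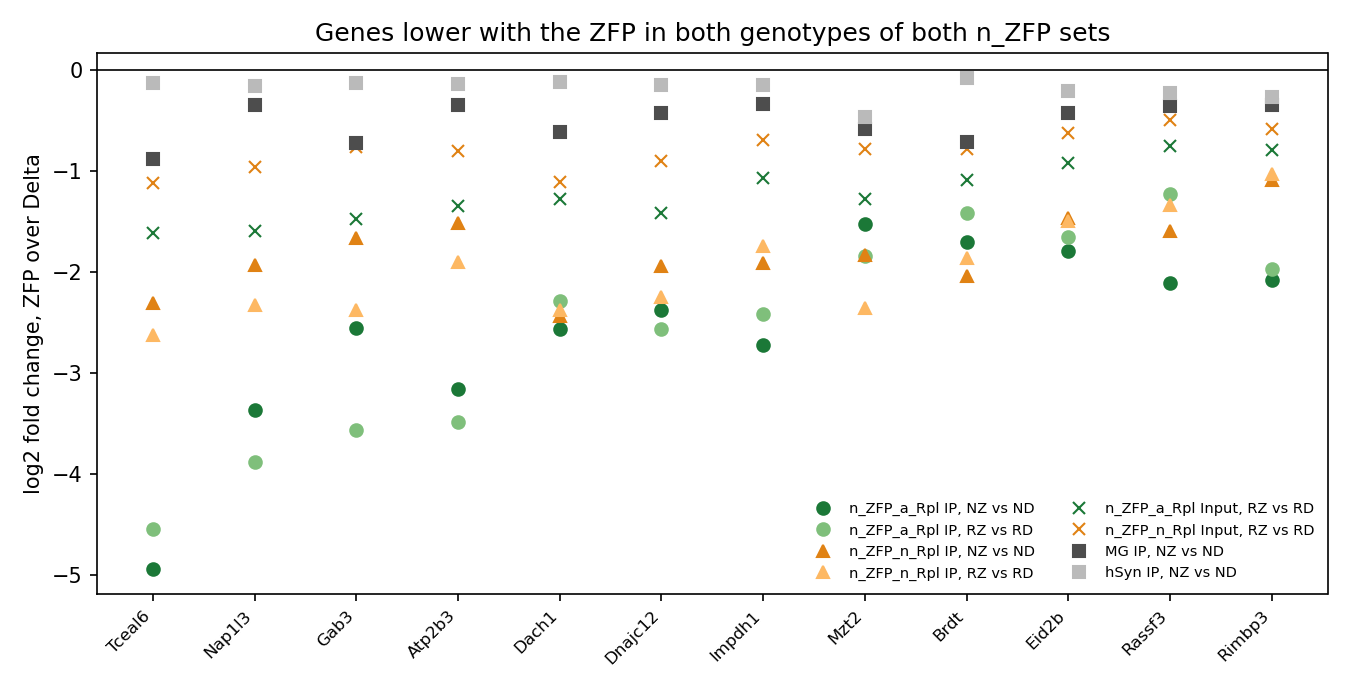
Log2 fold change with the ZFP of the genes that fell most among the 39 lower in both genotypes of both n_ZFP sets, with their values in the Inputs and the other sets.

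In the Inputs, RD against ND lowered 31, 32 and 32 of 33 projection neuron genes in the hSyn (3 and 5), n_ZFP_a_Rpl (3 and 4) and n_ZFP_n_Rpl (4 and 4) sets, with adjusted p = 0.0178, 0.000562 and 0.0718 with an estimated correlation. Ryr1 fell by 3.91 ± 0.08 in the n_ZFP_a_Rpl set and 4.11 ± 0.31 in the n_ZFP_n_Rpl set, and Abhd11os by 4.28 ± 0.16 and 5.18 ± 0.17 in the hSyn and n_ZFP_a_Rpl sets. Tpx2 rose by 2.16 ± 0.12 and 1.88 ± 0.15 in the n_ZFP sets, and AW551984 by 2.25 ± 0.34 in the hSyn set. Astrocyte markers fell in 19, 16 and 18 of 20 (0.101, 0.0102 and 0.0246 with an estimated correlation, the call of the hSyn set being lost). Over all genes 3625 rose and 3472 fell of 16090 in the hSyn set, 3851 and 3891 of 15780 in the n_ZFP_a_Rpl set and 4136 and 3742 of 15821 in the n_ZFP_n_Rpl set. The RZ against RD changes in IP and Input shared 1558 higher and 594 lower genes in the n_ZFP_a_Rpl set and 360 and 114 in the n_ZFP_n_Rpl set.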

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

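The tests of the projection neuron genes, of the genes lower with the ZFP and, for NZ against ND in the MG IP, of ND 1, 3 and 4 and of Rn45s were chosen after the results were seen, and the others before.

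The change of Tceal6, Cd4 and 2030 genes in all from RD to RZ differed between the astrocyte IPs. Of 100 splits of the libraries 4 gave as many, the real split included (highest other 2908), so that chance is unlikely but not excluded. The count was 3425 without MG RZ 1 and 1272 without n_ZFP_a_Rpl RD 2. Between the neuron IPs that change differed in 596 genes, Abhd11os and Egr2 among them, and chance cannot be excluded, with 6 of 100 splits as large and 1085 genes in the highest other (342 without hSyn RD 1, 388 without hSyn RZ 2, 395 without hSyn RZ 3 and 369 without n_ZFP_n_Rpl RZ 2). The change from ND to RD differed between neuron and astrocyte IPs in 3313 genes, Gfap among them, more than in any other of 60 splits (2964). The ZFP effect differed by genotype in 2512 genes of the n_ZFP_a_Rpl IP, Scn4b among them, where 4 of 100 splits were as large (highest other 3456). In the n_ZFP_n_Rpl IP it did so in 1989 genes, Nr4a1 among them (1195 without the doubted libraries), and no other of 100 splits was as large (1207).

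Some libraries stood apart from the rest of their group in the mean of a marker list, given here as the gap to the nearest library over the range of the group. Astrocyte markers set apart MG IP ND 1 (0.938), hSyn IP NZ 1 (0.886) and hSyn Input NZ 1 (0.853). Endothelial and mural markers set apart n_ZFP_a_Rpl IP ND 1 (0.92). Cortical excitatory markers set apart n_ZFP_a_Rpl Input NZ 2 (0.908), n_ZFP_n_Rpl Input NZ 2 (0.858), n_ZFP_n_Rpl IP NZ 2 (0.854) and n_ZFP_n_Rpl IP RZ 1 (0.839). Interferon response genes set apart hSyn IP ND 1 (0.713) and total counts n_ZFP_a_Rpl IP NZ 2 (0.833). Chance sets apart a library in about 1 in 20 groups, and 10 of 192 tests passed against 9.6 expected.

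Projection neuron genes rose in 32 of 33 in the astrocyte IP of the n_ZFP_a_Rpl set in RZ against RD (median 1.02), while 19 of 20 astrocyte markers fell. Carry-over of RNA from all other cells alike is argued against, since this list lies 5.81 log2 units above the microglia list in IP over Input (medians -0.08 and -5.89). A lower astrocyte share in RZ is argued against only as the sole cause. The highest median of the pan-neuronal, microglia and oligodendrocyte lists is 0.33, below the lower quartile of 0.86 of the projection neuron list. The projection neuron list also rose in the Input (median 0.67), and its excess in the IP has a median of 0.35. The pan-neuronal 0.33 is the change in the IP without the Input subtracted, so these values cannot be compared directly. A rise in the tissue together with a lower astrocyte share was not tested and stays open. Interneuron markers, outside that test, rose by a median of 0.72, and microglia, oligodendrocyte, endothelial and mural and cortical excitatory markers had medians of -0.12, -0.25, -0.12 and -0.06. The same change as in the Input is argued against by the mean of the list in the IP less that in the Input of the same number, which was higher by 0.36 in RZ than in RD (standard error 0.054 over 4 and 3 pairs). Of the 33 genes, 32 were larger in the IP and 5 passed the threshold when tested singly. Neuronal RNA that enters this pulldown by a route of its own and a change within the pulled-down cells stay open. An effect of the ZFP on these genes in R6/2 may be the biological explanation, as a hypothesis untested beyond this design.

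The 39 genes lower with the ZFP in both genotypes of both n_ZFP sets, with Tceal6 and Nap1l3 among them, stand against 0.0709 expected by chance overlap. For fewer cells of 1 marked type, the genes were set against 10 lists of cell type markers. The nearest list (choroid plexus and ependymal cells) lay above the genes by 5.54 of its standard errors in NCAR and 2.77 in R6/2 in the n_ZFP_a_Rpl set, and by 4.33 and 6.03 in the n_ZFP_n_Rpl set. The bound was 3 in at least 1 genotype, so that in R6/2 alone the n_ZFP_a_Rpl set does not meet it. The genes were picked for their fall in these same contrasts, and the standard errors are over genes of a list, not over libraries. These distances therefore cannot decide, and fewer cells of 1 type stay open. A change only in cells outside the pulldown is argued against in both sets by 65 genes picked in NCAR alone, as lower in NZ against ND in both IPs, and tested in the R6/2 libraries. The mean of IP less Input per pair differed between RZ and RD by -0.39 in the n_ZFP_a_Rpl set (standard error over pairs 0.039, with 55 genes below 0) and by -0.43 in the n_ZFP_n_Rpl set (0.031, with 59). The medians over genes were smaller, at -0.19 and -0.31, and 91 genes picked in the n_ZFP_n_Rpl set differed in the n_ZFP_a_Rpl set by a median of -0.13 (standard error over genes 0.058). RNA of other cells that enters the pulldown by a route of its own stays open. Binding of the ZFP at these genes may lower them, as a hypothesis, and a difference between the preparation of ZFP and Delta libraries, which the labels do not give, stays open.

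In the MG IP, 1081 genes passed the threshold for NZ against ND, Npsr1 and Prelp among them. The real split was the only 1 of 35 with as many, and the highest other gave 1. A share of 0.0286 is the smallest that 35 splits can give, so that chance is unlikely but not firmly excluded. The fold changes of the called genes kept a median of 0.975 of their size without ND 2 and at least 0.989 without ND 1, 3 or 4. These genes were picked by a test against the spread within groups, which genes carried by 1 library seldom pass. The ratios therefore cannot decide whether a single ND library is the source of the count. Most calls ended when any of these libraries was left out. The median standard error was 0.098 with all libraries and 0.108 to 0.109 without one of these, and all 1081 genes had an unadjusted p below 0.05 each time, but what ended the calls was not tested. The higher depth of the NZ libraries (means of 62.6 M and 52.2 M counts) is argued against by 994 genes with all libraries thinned to 45.1 M. An axis along which the libraries within RD and within RZ also differ may add to the count and cannot be told apart, since its correlation across genes with the change was 0.307 in size, between the bounds set for it. Rn45s took 0.105% to 0.314% of the counts in ND, 0.0306% to 0.0881% in NZ, 0.0409% to 0.0661% in RD and 0.0241% to 0.0409% in RZ. A difference in preparation marked by this share cannot be told apart, since it goes with the groups and the correlation of the change with the slope on the share within groups was 0.206, between the same bounds. Leaving out ND 1 gave 26 genes, ND 2 19, ND 3 127, ND 4 407, NZ 2 2057, NZ 3 32 and NZ 5 50. An effect of the ZFP in NCAR mice stays open as untested.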

How the results depend on the processing

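The test without the doubted libraries was chosen after the data were seen, and the other alternatives before. No named gene or signature shift reversed past its threshold under any alternative run, and other genes were not compared singly. The larger direction of some counts turned. With RLE factors the MG IP gave 470 higher and 626 lower for NZ against ND (565 and 516 as reported), and 2362 and 2632 for RD against ND (2663 and 2480). For RD against ND it gave 3465 and 3546 in the hSyn Input (3625 and 3472), 3782 and 3959 in the n_ZFP_n_Rpl Input (4136 and 3742) and 1623 and 1670 between neuron and astrocyte IPs (1845 and 1468). DESeq2 turned these 5 counts too, fits of only the 2 groups the first 4 and the replicate block both of the MG IP. Some fits that left out libraries turned counts of the IPs as well. Of the counts, 448 alternatives stayed within 1.5 times the reported value and 67 did not, and of the named genes 8310 kept their side of the threshold, 611 lost it and 18 gained it. With DESeq2 and its size factors the MG IP gave 391 genes for RZ against RD (223 higher and 168 lower, against 2 and 10), 2251 for NZ against ND and 52 for the interaction. The hSyn IP gave 22 for RZ against RD (12 higher and 10 lower, against 1 and 5), 10 for NZ against ND (2 higher and 8 lower, against 0 and 4) and 7 for the interaction, and the hSyn Input gave 5 for RZ against RD. DESeq2 also gave 875 and 1751 for NZ against ND in the n_ZFP_a_Rpl and n_ZFP_n_Rpl IPs, 901 for RZ against RD in the n_ZFP_n_Rpl Input and 1006 for the difference between the neuron IPs. In fits of only the 2 groups compared, which have fewer samples, the MG IP gave 1 and the hSyn IP 10 genes for RZ against RD, and the hSyn Input gave 1. NZ against ND gave 2 in the hSyn IP, 146 in the n_ZFP_a_Rpl IP and 241 in the n_ZFP_n_Rpl IP. With no filter the MG interaction gave 1 gene. Without the doubted libraries RZ against RD in the hSyn IP gave 14 (7 higher), NZ against ND in the n_ZFP_n_Rpl IP 572 and the interaction there 1195. For these counts the cause was not tested.

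Leaving out each library in turn gave 5 to 2043 genes in the MG IP for RZ against RD, 19 to 2057 for NZ against ND and 0 to 3 for the interaction. It gave 0 to 4 in the hSyn IP for RZ against RD, 0 to 1 for the interaction and 0 to 1 in the hSyn Input for RZ against RD. NZ against ND ranged from 151 to 641 in the n_ZFP_a_Rpl IP and from 524 to 1313 in the n_ZFP_n_Rpl IP. RZ against RD ranged from 1677 to 2297 in the n_ZFP_a_Rpl Input and from 216 to 516 in the n_ZFP_n_Rpl Input. The difference between the astrocyte IPs ranged from 1272 to 3425 and that between the neuron IPs from 342 to 629. The n_ZFP_a_Rpl signature in the MG IP ranged from -0.093 to -0.062, and with its 200 genes of smallest p it was -0.163 (fry p 0.0871).

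Across conditions, libraries with the same number did not deviate together (median correlations across genes of -0.03 to 0.061), so they share only a number. With that number as a replicate block, RZ against RD gave 6 genes in the MG IP and 1 in the hSyn IP, and NZ against ND gave 3 in the MG IP. For IP against Input, the replicate block gave 3254 and 2798 genes in the n_ZFP_a_Rpl and n_ZFP_n_Rpl sets and 2647 in the hSyn set. There the number is not a pair in ND, since IP ND 1, 2, 3 and 4 correlated best with Input ND 2, 3, 4 and 5 (0.42 to 0.56), and IP NZ 5 did with Input NZ 4, so this block joins ND libraries that do not match. It moved no other count by more than 1.5 times. Camera called 296 lists over all comparisons, 76 with an estimated correlation and 259 by fry. A term for sex was not run, since all libraries carry the same sex markers. At the depth of the MG IP, 41.8% of the interactions of 1.5-fold planted among 15238 simulated genes were recovered, so interactions of that size can be missed.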

Other observations

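The groups of genes described here were chosen after the results were seen, and the other splits of the libraries before.

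Of 979 genes more than 2-fold higher in the n_ZFP_a_Rpl IP than in its Input, 368 fell and 52 rose in RZ against RD (median -0.30), while 1800 fell and 2710 rose of the 12898 genes in between and 68 fell and 152 rose of 1339 more than 2-fold lower. In RD against ND 235 of the 979 fell and 141 rose, and in NZ against ND 8 fell and 3 rose (median -0.125). The classes were not compared by a test. In the MG IP, 4 of 975 such genes fell and 0 rose in that comparison, 148 fell and 53 rose in RD against ND, and 69 rose and 7 fell in NZ against ND. The mean log2 CPM of the projection neuron list in the n_ZFP_a_Rpl IP was 8.44 in ND, 8.46 in NZ, 7.01 in RD and 8.09 in RZ (SD between libraries 0.10, 0.16, 0.21 and 0.07), and in the MG IP it was 8.32, 7.95, 6.87 and 6.94 (SD 0.03, 0.34, 0.21 and 0.10). In the n_ZFP_n_Rpl IP it was 8.80, 7.45 and 7.98, with 8.38 in NZ, and in the hSyn IP 9.12, 7.88 and 7.85, with 9.13 in NZ.

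The 39 genes lower with the ZFP in the n_ZFP sets, such as Tceal6, leaned the same way in the other sets at smaller size. In the MG IP 34 of them were negative in NZ against ND (median -0.26) and 29 in RZ against RD (median -0.17), and in the hSyn IP 36 were negative in each (medians -0.09 and -0.12). Of the genes lower in NCAR with the ZFP, 65 were shared by the n_ZFP sets (5.88 expected), and of those higher 10 (5.28 expected). In the n_ZFP_n_Rpl IP, 122 genes lower in NZ against ND were higher in RZ against RD (64.5 expected), beside 91 lower in each (54.2 expected).

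Other splits of the same libraries bear on the remaining counts. For RD against ND chance is unlikely in each IP and Input, since no split but the real 1 gave as many genes. For the IPs together it can be excluded, since 1300 genes rose and 1656 fell in all 4 (37.3 and 40.9 expected). The real and highest other values were 5143 and 6 in the MG IP, 7820 and 6 in the hSyn IP, 6907 and 3631 in the n_ZFP_a_Rpl IP and 7772 and 81 in the n_ZFP_n_Rpl IP. In the Inputs they were 7097 and 12, 7742 and 3806, and 7878 and 0 in the hSyn, n_ZFP_a_Rpl and n_ZFP_n_Rpl sets. For IP against Input chance is unlikely too, with 2618 and 1, 3250 and 1, and 2792 and 949 genes in these sets. The shift of the MG genes in the n_ZFP_a_Rpl IP (-0.326, highest other 0.236 in size), of the hSyn genes in the n_ZFP_n_Rpl IP (-0.232, 0.143) and of the n_ZFP_a_Rpl genes in the MG IP (-0.075, 0.068) exceeded those of other splits. The last was not past its threshold without MG RD 1 (-0.066), RD 3 (-0.062), RZ 1 (-0.072) or RZ 2 (-0.074). For the n_ZFP_n_Rpl genes in the hSyn IP (-0.033, highest other 0.04) chance cannot be excluded, with 4 of 35 splits as large.

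For RZ against RD the splits make chance unlikely in the n_ZFP_a_Rpl IP (5151 genes, highest other 1862). They do so too in its Input (2545 and 690, with 1677 without RD 2) and in the n_ZFP_n_Rpl IP (2635 and 0). Chance is also unlikely in the n_ZFP_n_Rpl Input (525 and 0). The count there was 308 without RD 2, 306 without RD 3, 260 without RD 4, 336 without RZ 1 and 216 without RZ 2. In the hSyn IP, with Abhd11os highest, no other split gave as many as the 6 genes (highest other 1). That count was 0 without RD 1, RD 3 or RZ 2, 2 without RD 2, RZ 1 or RZ 3 and 14 without the doubted libraries, so that chance is not firmly excluded. For the count of the MG IP it cannot be excluded, since 3 of 35 splits gave at least 12 genes, and 1625 in the highest other point to a structure of the samples. For 9 of these 12 genes it can, since 8 were also lower (0.336 expected) and 1 also higher (0.0737 expected) in NZ against ND, which uses other libraries, and 0 went in opposite directions. Both comparisons go with the share of Rn45s, which was lower in NZ than in ND and 0.0241% to 0.0409% in RZ against 0.0409% to 0.0661% in RD. That count was 5 without RD 2 or RD 3, 2043 without RZ 1, 6 without RZ 2 and 7 without RZ 4. In the hSyn Input edgeR's quasi-likelihood test called 0 genes (628 at an unadjusted p below 0.05, 5 by DESeq2, 1 without RD 1), so that all 35 splits were as large, with 1 gene in the highest other.

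For NZ against ND chance is unlikely in the n_ZFP_a_Rpl IP, where 316 genes compare with 150 in the highest other split. The count was 203 without ND 2, 641 without NZ 3 and 151 without NZ 4. Chance is also unlikely in the n_ZFP_n_Rpl IP, where 1113 genes compare with 1. That count was 599 without ND 3, 524 without NZ 2, 638 without NZ 3 and 572 without the doubted libraries. For the count of the hSyn IP, where A2m and Cyp2j6 fell, chance cannot be excluded, since 8 of 100 splits gave at least 4 genes. The 288 in the highest other point to a structure of the samples. For the 4 genes chance can be excluded, since all were also lower in NZ against ND in the MG IP (0.137 expected). In RZ against RD in the hSyn IP 2 were also lower (0.0013 expected). For the interaction edgeR's quasi-likelihood test called 0 genes in the MG IP (1143 at an unadjusted p below 0.05, 52 by DESeq2), so that all 100 splits were as large, and 2127 in the highest other point to a structure of the samples. Leaving out NZ 4, RZ 1 or RZ 4 gave 1 gene there, RD 1 2 and RD 4 3. In the hSyn IP it called 0 (646 at an unadjusted p below 0.05, 7 by DESeq2, 1 without RZ 4), with 14 in the highest other split.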
